A study of Mus musculus with 6 samples.

How the data were processed

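Total RNA of CD11c-positive conventional DCs, sorted by organ from BALB/c mice, was measured on 6 Affymetrix 3′ arrays, 3 per organ. Per the labels' protocols, RNA was extracted with TRIzol and a column clean-up with 20 ng of carrier RNA, only preparations with an RNA integrity number above 8.4 were used, and 2 ng of total RNA was amplified into biotinylated cDNA. The deposited values are intensity summaries of probe sets on a linear scale, rounded to 1 decimal and alike in median and quartiles between arrays. Per the submitters' processing notes, RMA and limma were used, with versions not given in the sources used here. RMA returns log2 values, so the deposited intensity must have been brought back to the linear scale, and whether a floor or further scaling was applied stays unknown. Array medians were 39.4 to 41.3, and no detection calls were used. The number of arrays limits the precision of every value.

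The table held 22690 probe sets, of which 64 were controls. The array annotation gave 1 gene symbol for 20393 probe sets, several for 691 and none for 1606, controls included. Of those with 1 symbol, 20364 were found through their Entrez identifier in a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. That table served for names only, and no genome coordinates are given because the files name no build. Each of 12394 genes was represented by its probe set with the highest mean over all 6 arrays; 4958 genes had more than 1 probe set, at most 11. Of 190 genes past the threshold with several probe sets, 175 had the same sign in all of them. No filter on level was applied, and a list member without a named probe set was not analysed here.

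Groups were taken from the sample titles. The intensity values were transformed to log2, and arrays labelled spleen were compared with arrays labelled lymph node in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, neither trend nor robust), two-sided, with Benjamini-Hochberg adjustment over all genes or probe sets and a threshold of 0.05. Folds are ratios of geometric means on the deposited scale. Gene lists (34) and cell type marker lists (15) were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of each kind, where at least 5 members were measured. Beside it stood camera with a correlation estimated per list, with which 0 gene lists and 0 marker lists passed. The other test was fry, which tests whether a list's genes move one way on balance without comparing them with other genes, and with which 9 gene lists and 0 marker lists passed. Median, mean and camera direction differed in sign for 5 gene lists and 1 marker list, 0 of which passed. Control probe sets were compared with exact permutation tests.

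The lists, the tests and the rule for named genes were fixed before the data were examined. The rule takes, among genes past the threshold whose groups do not overlap and whose higher group mean is above the median of all genes, the 12 with the largest log2 difference in each direction. It adds, in each list that passes, or has at least 3 members past the threshold, up to 4 members with the smallest adjusted p, and in other lists up to 2. It ends with 12 fixed genes, namely Itgax, Ccr7, Cd8a, Itgae, Sirpa, Itgam, Irf4, Irf8, Cd40, H2-Ab1, Cd4 and Aldh1a2. Alternatives were median centring, a second quantile normalization, a filter at the median level, eBayes with trend and robust, array weights, a replicate block, each array left out, the mean of all probe sets of a gene, a 2-fold minimum and a threshold of 0.01. Others were added after seeing the data: log2 of the value plus 16, both arrays numbered 3 left out, the level of the bacterial poly-A controls or of the plasmacytoid DC markers as a covariate, and probe sets with the suffixes for cross-hybridising designs left out. The functions were tested on simulated data for this comparison, drawn for 12394 genes from their real means and spreads with 200 genes changed. Of the genes changed by 1, 2 and 3 log2 units, 52.2%, 86.6% and 98.5% were recovered, and 7.06% of the 170 calls were unchanged genes. The simulated noise was independent between genes, while real genes varied together within groups, so these rates may not hold for the real data.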

Results

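Gene expression was measured on Affymetrix 3′ microarrays in dendritic cells of BALB/c mice, an inbred laboratory strain. Dendritic cells (DCs) are antigen-presenting cells of the immune system. The conventional DCs studied here were sorted by flow cytometry as CD11c-positive cells, CD11c being the integrin encoded by Itgax. Spleen and lymph node were each represented by 3 arrays, numbered 1 to 3 in the labels. The labels do not say whether the arrays came from separate animals or pools, so the p-values measure only the spread between these arrays, which may be technical. Array medians lay between 39.4 and 41.3 intensity units, and the 3 arrays per group limited the precision. Pearson correlations of log2 intensity across probe sets were 0.982 to 0.991 among arrays labelled lymph node, 0.967 to 0.978 among arrays labelled spleen and 0.953 to 0.973 between the groups. The first principal component held 50% of the variance and separated the groups.

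The comparison asked how the transcriptomes of conventional DCs from spleen and lymph node differ. The chemokine gene Ccl22 was 31.3-fold higher in the arrays labelled spleen, with a log2 intensity of 9.34 ± 0.07 (SD, n = 3) against 4.37 ± 0.28 (SD, n = 3) in the arrays labelled lymph node (adjusted p = 7.92e-05). Aldh1a2, the retinaldehyde dehydrogenase that makes retinoic acid, was 26.6-fold higher in the same arrays, at 8.86 ± 0.12 against 4.12 ± 0.47 (SD, n = 3 each; adjusted p = 0.000529). In the other direction, the adaptor gene Sash1 was 8.82-fold higher in the arrays labelled lymph node, at 10.47 ± 0.13 against 7.33 ± 0.53 (SD, n = 3 each; adjusted p = 0.00371), and Dtx1, a Notch target gene, was 8.01-fold higher there (adjusted p = 0.00528). Ccl22, Ccr7 and Fscn1 are textbook genes of the migratory DCs that reach lymph nodes from tissues. All 3 were higher in the arrays labelled spleen, Fscn1 in 3 of its 4 probe sets, which goes against the labels. The groups are therefore called arrays labelled spleen and arrays labelled lymph node, and every difference is spleen minus lymph node as labelled.

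In total, 421 of 12394 genes passed an adjusted p of 0.05 in limma, 251 higher in arrays labelled spleen and 170 higher in arrays labelled lymph node, and 342 of them differed at least 2-fold. At the level of probe sets, 630 of 22626 passed. All 421 genes had groups that did not overlap, as did 24.5% of all genes, where chance gives 10%. The count fell to 57 without lymph node array 1, to 50 without lymph node array 2 and to 130 without spleen array 1. It was 0 with the level of the bacterial poly-A control probe sets as a covariate in limma, a fit added after seeing the data, in which 701 genes had an unadjusted p under 0.05. That level separates the groups without overlap and leaves 3 residual degrees of freedom. The fit therefore cannot decide whether the genes follow that level or the labels. For 75 of the 421 genes the lower group mean was under 4 on the log2 scale, near the 2.01 to 2.20 of a control transcript at the bottom of the scale. Their folds rest on values close to background, and Blnk, Ido1, Cldn1, Il15 and Ifi204, given below as folds, are among them.

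**Figure D1:**
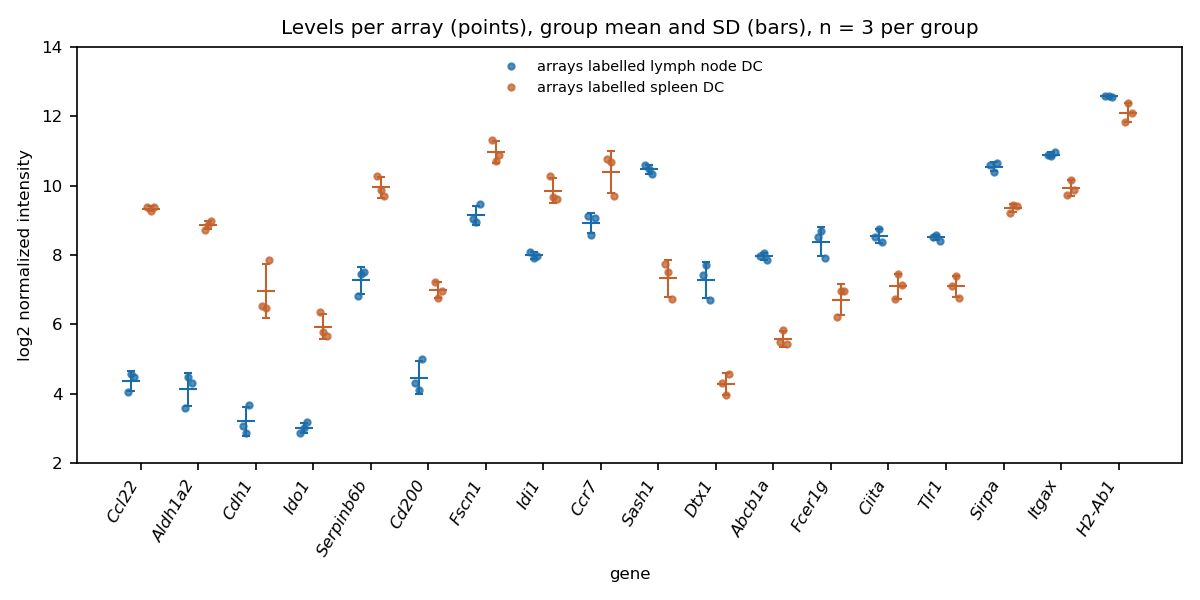
Log2 normalized intensity of 18 genes on each array (points), with the group mean and SD (bars, n = 3) for arrays labelled lymph node (blue) and spleen (orange). Ccl22 lies at 9.34 on average in arrays labelled spleen and at 4.37 in arrays labelled lymph node, and Sash1 at 7.33 and 10.47; H2-Ab1 did not pass the threshold.

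Among the 12 genes with the largest difference towards the arrays labelled spleen, Ccl22 and Aldh1a2 were joined by Gzmc (log2 difference 4.45 ± 0.46 SE, adjusted p = 0.00584), a granzyme gene of cytotoxic cells, and by Cdh1 (3.75 ± 0.39 SE, adjusted p = 0.00589), which encodes E-cadherin. Plppr4 (4.09), Laptm4b (3.89), Rai2 (3.85) and Glipr2 (3.76) were also among them. The others were D13Ertd608e at 5.56 ± 1.11 (SE, adjusted p = 0.0404), Cd28, a costimulatory receptor of T cells, at 4.07, Klk1 at 4.06 and Sdc1, the syndecan of plasma cells, at 3.93. D13Ertd608e lay at 3.14, 3.25 and 7.45 in the lymph node arrays and passed in only 1 of the 6 fits with 1 array left out. Gzmc, Plppr4, Cd28, Sdc1, Rai2 and Cdh1 had means under 4 in the arrays labelled lymph node, so the size and order of their differences are uncertain. The 12 largest differences towards the arrays labelled lymph node included Adamdec1 (-3.16), Sash1 (-3.14), Dtx1 (-3.00), the ion cotransporter gene Slc12a2 (-2.97), the macrophage elastase gene Mmp12 (-2.79) and Scel (-2.42). After these came the transglutaminase gene Tgm2 (-2.38), the drug efflux pump gene Abcb1a (-2.38), Arhgap6 (-2.22), Cd22 (-2.13), Bex6 (-2.01) and the inhibitory lectin gene Siglece (-1.98). Ccl22, Aldh1a2, Gzmc, Plppr4, Laptm4b, Glipr2, Cdh1, Sash1, Dtx1 and Abcb1a passed the threshold whichever single array was left out. The other 14 of these 24 genes lost it without at least 1 array.

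The list of migratory and mature DC genes was higher in the arrays labelled spleen. Of its 33 measured members 13 were higher and 0 lower (24 higher and 1 lower adjusted over the list alone), with a median log2 difference of 0.94 (camera adjusted p = 7.71e-13; adjusted p = 0.313 with an estimated correlation). Besides Ccl22, these included Serpinb6b (6.41-fold, adjusted p = 0.00528), the inhibitory surface glycoprotein gene Cd200 (5.75-fold, adjusted p = 0.00582) and Fscn1 (3.52-fold, adjusted p = 0.00946), which encodes the actin-bundling protein fascin of mature DCs. Only 3 of the 4 probe sets of Fscn1 had that sign. Ccr7, the chemokine receptor that guides DCs to lymph nodes, was 2.77-fold higher (10.39 ± 0.60 against 8.92 ± 0.29, SD, n = 3 each) and passed narrowly (adjusted p = 0.0496, 0.0122 to 0.19 with 1 array left out). The costimulatory gene Cd40 differed by 0.76 ± 0.18 (SE) and did not pass (adjusted p = 0.0660). The plasmacytoid DC markers (median difference 1.39) and the bacterial poly-A control probe sets (mean difference 1.11) were higher in the same arrays.

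Genes of skin-derived DCs and Langerhans cells were also higher there, 6 of 18 measured members and 0 lower, which was likewise 6 higher but 1 lower adjusted over the list alone (median 0.84, camera adjusted p = 0.000319; adjusted p = 0.313 with an estimated correlation). Aldh1a2, Cdh1, the tight junction gene Cldn1 (4.05-fold, adjusted p = 0.0101) and the lectin gene Clec10a (6.31-fold, adjusted p = 0.0196) had the smallest adjusted p. The filter at the median level ended the call on the list of skin-derived DCs and Langerhans cells (adjusted p = 0.264). Of the tolerance-associated genes 5 of 20 were higher and 0 lower (5 higher and 1 lower adjusted over the list alone; median 0.25, camera adjusted p = 0.0437; adjusted p = 0.573 with an estimated correlation). Its leading members were Ido1, the tryptophan-degrading enzyme indoleamine dioxygenase (7.54-fold, adjusted p = 0.00350), Cd200 and Lgals1, the gene of galectin-1 (2.50-fold, adjusted p = 0.0212). Socs3 was 5.64-fold higher by its brightest probe set, but only 2 of its 3 probe sets had that sign. The call on the tolerance list was lost in 13 of 20 alternatives, among them median centring (adjusted p = 0.0553), a second quantile normalization (0.0516), a filter at the median level (0.591) and fry (0.0670). It was also lost without lymph node array 1 (adjusted p = 0.117), lymph node array 2 (0.0521), spleen array 1 (0.122) or spleen array 2 (0.0800), with medians down to 0.11. The plasmacytoid DC markers and the poly-A controls moved with these lists too.

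Chemokine genes were higher in the arrays labelled spleen for 3 of 19 members and lower for 0 (5 higher and 1 lower adjusted over the list alone; median 0.35, camera adjusted p = 0.00775; adjusted p = 0.536 with an estimated correlation). The call was lost without spleen array 2 (median 0.20, adjusted p = 0.136; 0.64 without spleen array 3) and with the filter at the median level (0.0902). The members were Ccl22, Cxcl16 (2.88-fold, adjusted p = 0.0304) and Ccl17 (1.91-fold, adjusted p = 0.0343). Of 19 chemokine and migration receptors 2 were higher and 0 lower (6 higher and 1 lower adjusted over the list alone; median 0.27, camera adjusted p = 0.0410; adjusted p = 0.589 with an estimated correlation). They were Ccr7 and Ccr9, a gut-homing receptor that is also a plasmacytoid DC marker (6.92-fold, adjusted p = 0.0385). This call was lost without spleen array 1 (median 0.062, adjusted p = 0.265) or 2 (median 0.15, adjusted p = 0.0782), and the median was 0.68 without spleen array 3. Fry (adjusted p = 0.299), the offset of 16 (0.103) and leaving out cross-hybridising probe sets (0.0567) ended it too. Cholesterol synthesis genes were higher for 4 of 15 members and lower for 0 (6 higher and 0 lower adjusted over the list alone; median 0.46, camera adjusted p = 5.10e-05; adjusted p = 0.313 with an estimated correlation). These were Idi1 (3.63-fold, adjusted p = 0.00762), Sqle (2.55-fold, adjusted p = 0.0264), Fdft1 (1.75-fold) and Hmgcs1 (1.76-fold), enzymes of the mevalonate and sterol pathway. The plasmacytoid DC, T cell and NK cell markers and the poly-A controls were higher in the same arrays as these lists.

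Genes of the CD8 lineage (cDC1) and of the CD11b lineage (cDC2) of conventional DCs were tested as separate lists. The cDC1 list had a median of 1.16, but 0 of its 16 members passed over all genes (9 higher and 1 lower adjusted over the list alone; camera adjusted p = 3.79e-05; adjusted p = 0.586 with an estimated correlation). Its call was also lost with fry (adjusted p = 0.261), and the median lay between 0.79 and 1.36 with 1 array left out. Cd8a differed by 1.57 ± 0.40 (SE, adjusted p = 0.0821) and Irf8, the transcription factor of the lineage, by 1.67 ± 0.56 (adjusted p = 0.156). Itgae, the integrin CD103, differed by 1.18 ± 0.46 (adjusted p = 0.218) and Batf3 by -1.05 ± 0.28 (adjusted p = 0.0920). In the cDC2 list 3 of 18 members were lower in the arrays labelled spleen and 1 higher (8 lower and 2 higher adjusted over the list alone; median -0.59, camera adjusted p = 0.0133; adjusted p = 0.313 with an estimated correlation). Dtx1, Sirpa (-1.19 ± 0.16 SE, adjusted p = 0.0121), the inhibitory receptor that marks cDC2, and Cd300a (-1.19 ± 0.18, adjusted p = 0.0201) were lower, and Clec10a was higher. The poly-A controls and plasmacytoid DC markers were higher in the arrays labelled spleen, and the cDC2 call was lost with the level of either as a covariate (median -0.41, adjusted p = 0.308, and -0.23, adjusted p = 0.276). It was also lost without both arrays numbered 3 (adjusted p = 0.115). Irf4, with -0.79 ± 0.235 (adjusted p = 0.115), Cd4, with -0.53 ± 0.33 (adjusted p = 0.442), and Itgam, which encodes CD11b, with 0.10 ± 0.23 (adjusted p = 0.866), did not pass. Itgax itself was 1.96-fold higher in the arrays labelled lymph node (10.90 ± 0.06 against 9.93 ± 0.22, SD, n = 3 each; adjusted p = 0.0310). The Notch-dependent splenic DC genes had 1 member higher, Dll1, and 1 lower, Dtx1, of 12, and a median of -0.053 (camera adjusted p = 0.951).

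Genes of MHC class II presentation were lower in the arrays labelled spleen for 3 of 12 members and higher for 0 (8 lower and 0 higher adjusted over the list alone; median -0.55, camera adjusted p = 0.000109; adjusted p = 0.421 with an estimated correlation). The 3 were Ciita, the transactivator of the class II genes (2.72-fold lower, adjusted p = 0.0196), H2-Oa (2.78-fold, adjusted p = 0.0266) and H2-DMa (2.33-fold, adjusted p = 0.0498). The class II chain gene H2-Ab1 differed by -0.47 ± 0.18 (SE, adjusted p = 0.210). Fc and complement receptors were lower for 3 of 15 members and higher for 0 (5 lower and 0 higher adjusted over the list alone; median -0.22, camera adjusted p = 0.0266; adjusted p = 0.313 with an estimated correlation). They were Fcer1g, the common signalling chain of Fc receptors (-1.66 ± 0.29 SE, adjusted p = 0.0304), Itgax and Cr2 (-1.60 ± 0.33, adjusted p = 0.0466). The median was -0.060 without lymph node array 1 and -0.33 without lymph node array 2. This call was lost with log2 of the value plus 16 (adjusted p = 0.0536), without both arrays numbered 3 (0.1) and with the poly-A level as a covariate (0.279). Of 18 Toll-like and other pattern receptor genes 1 was lower and 0 higher, also adjusted over the list alone (median -0.35, camera adjusted p = 0.0410; adjusted p = 0.313 with an estimated correlation). That gene was Tlr1 (-1.41 ± 0.19, adjusted p = 0.0131). The list's call was lost without lymph node array 2 (adjusted p = 0.0521) or 3 (0.0609) or spleen array 2 (median -0.22, adjusted p = 0.0779). Ribosomal protein genes had a median of -0.30 with 0 of 15 members past the threshold (3 lower and 0 higher adjusted over the list alone; camera adjusted p = 0.00775; adjusted p = 0.722 with an estimated correlation). A second quantile normalization ended this call (median -0.20, adjusted p = 0.0721), as did fry (0.224), and the median lay between -0.42 and -0.20 with 1 array left out. The poly-A controls and the plasmacytoid DC markers were higher in the arrays labelled spleen, where these lists were lower. With the poly-A level as a covariate the MHC class II median was -0.12 (adjusted p = 0.488), and with the plasmacytoid DC marker level it was -0.42 (adjusted p = 0.0975).

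**Figure D2:**
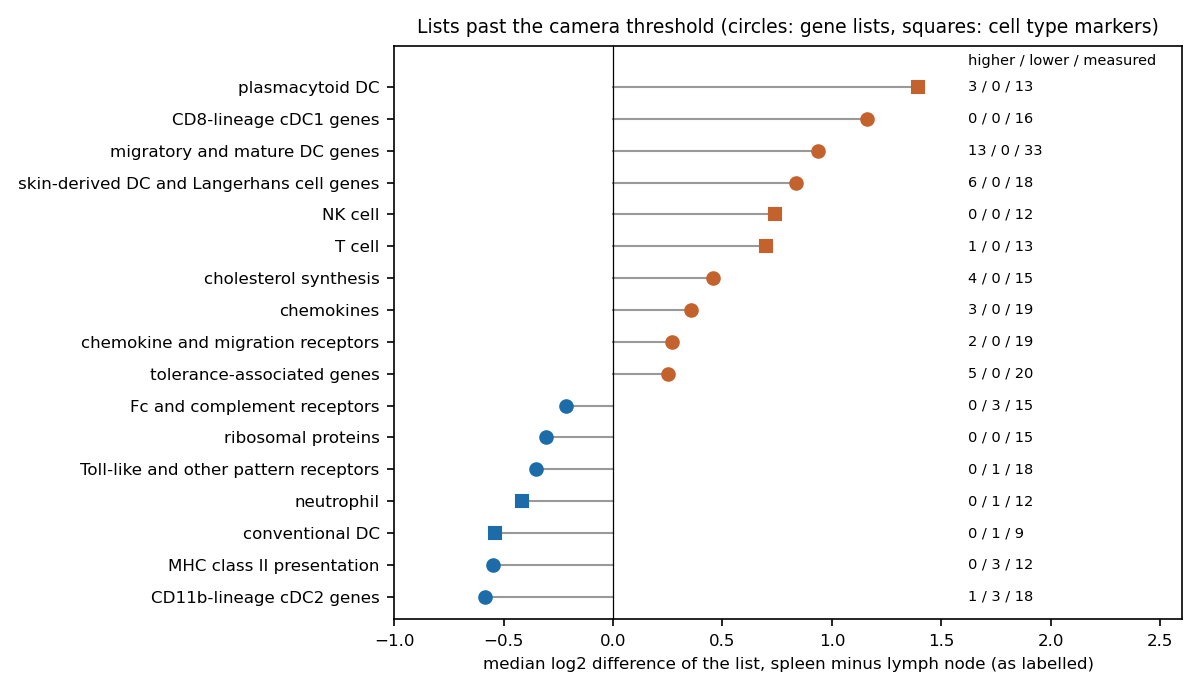
Median log2 difference, spleen minus lymph node as labelled, of the 12 gene lists (circles) and 5 cell type marker lists (squares) past the camera threshold, with the number of members higher, lower and measured. The medians run from -0.59 for cDC2 genes to 1.39 for plasmacytoid DC markers, and all 17 calls were lost with an estimated correlation.

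Markers of other cell types differed between the groups as well. Plasmacytoid DC markers were higher in the arrays labelled spleen for 3 of 13 members and lower for 0 (7 higher and 0 lower adjusted over the list alone; median 1.39, camera adjusted p = 0.000108; adjusted p = 0.507 with an estimated correlation). The 3 were Blnk (12.1-fold, adjusted p = 0.0119), Klk1 (16.6-fold, adjusted p = 0.0351) and Ccr9, and the median was 0.90 without spleen array 3. Blnk had a mean of 2.99 in the arrays labelled lymph node, close to background, so the size of its fold is uncertain. T cell markers were higher for 1 of 13 members, Cd28, and lower for 0 (3 higher and 0 lower adjusted over the list alone; median 0.70, camera adjusted p = 0.0103; adjusted p = 0.507 with an estimated correlation). This call was lost without spleen array 1 (median 0.21, adjusted p = 0.148). NK cell markers had a median of 0.74 with 0 of 12 members past the threshold, also adjusted over the list alone (camera adjusted p = 0.0273; adjusted p = 0.507 with an estimated correlation). This call was lost without lymph node array 1 (adjusted p = 0.0727), lymph node array 2 (0.0845) or spleen array 1 (median 0.24, adjusted p = 0.440), and the median was 1.25 without spleen array 3. Neutrophil markers were lower for 1 of 12 members, Camp, and higher for 0 (4 lower and 0 higher adjusted over the list alone; median -0.42, camera adjusted p = 0.00518; adjusted p = 0.507 with an estimated correlation). S100a9 differed by -3.44 ± 0.76 (SE, adjusted p = 0.0536). Conventional DC markers were lower for 1 of 9 members, Itgax, and higher for 0 (4 lower and 0 higher adjusted over the list alone; median -0.54, camera adjusted p = 0.00114; adjusted p = 0.507 with an estimated correlation). With the poly-A level as a covariate the medians were -0.049 for conventional DC markers (adjusted p = 0.589), -0.097 for plasmacytoid DC markers (0.765), 0.069 for T cell markers (0.775) and -0.61 for NK cell markers (0.589). With the plasmacytoid DC level the conventional DC call was lost as well (adjusted p = 0.147), and 0 marker lists passed with fry. With 1 array left out, the conventional DC median lay between -0.71 and -0.34.

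**Figure D3:**
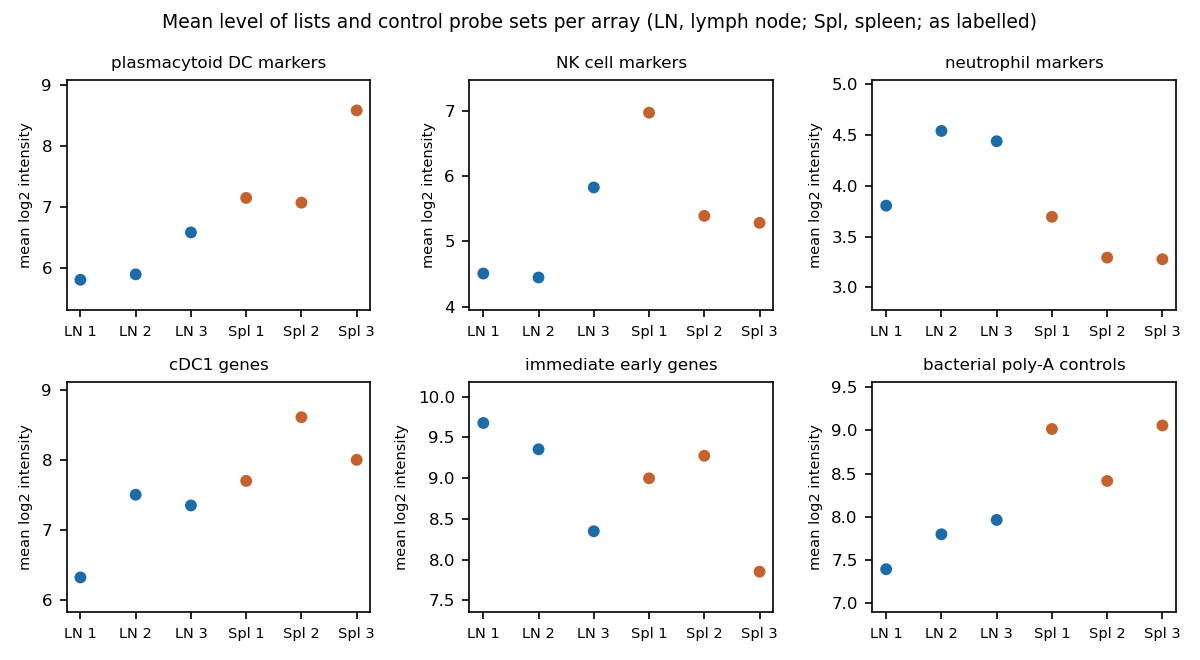
Mean log2 intensity of 5 lists and of the bacterial poly-A control probe sets on each array, coloured by the labelled organ (blue, lymph node; orange, spleen). Plasmacytoid DC markers lie between 5.80 and 6.58 in arrays labelled lymph node and between 7.07 and 8.59 in arrays labelled spleen, and the poly-A controls between 7.39 and 7.96 and between 8.41 and 9.06.

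Of the 12 gene lists past camera, 8 also passed fry, which does not compare a list with other genes (adjusted p from 0.0210 to 0.0457). They were the cDC2, migratory, skin-derived DC, MHC class II, chemokine, Toll-like receptor, Fc receptor and cholesterol synthesis lists. The cDC1, chemokine receptor, tolerance and ribosomal lists did not pass fry. The remaining 22 gene lists and 10 cell type marker lists did not pass camera, with adjusted p from 0.105 to 0.999 and from 0.139 to 0.935. The cell cycle list, with a median of 0.083 (camera adjusted p = 0.547), passed without lymph node array 2 (0.33, adjusted p = 0.0353) and without spleen array 3 (0.52, adjusted p = 0.00432), and was -0.14 without lymph node array 3. It also passed with the poly-A level (0.89, adjusted p = 5.73e-05) or the plasmacytoid DC level (1.12, adjusted p = 9.59e-09) as a covariate. Single members of the remaining lists passed. Among costimulatory and checkpoint genes, the ligand gene Icosl (-1.07 ± 0.16 SE, adjusted p = 0.0170) and Cd244a (-1.12 ± 0.18, adjusted p = 0.0223) were lower in the arrays labelled spleen and Slamf1 was higher (2.35 ± 0.43, adjusted p = 0.0331). Among cytokine genes, Il15, a growth factor of T and NK cells, was 5.79-fold higher (adjusted p = 0.0378) and Tnf 2.22-fold lower (adjusted p = 0.0414). Cd44, a hyaluronan receptor, was 2.70-fold higher (adjusted p = 0.0119), and Hpgds, a prostaglandin D synthase gene, 3.33-fold lower (adjusted p = 0.0128). Across every part of the naming rule, 14 of the 76 genes past the threshold kept that side whichever array was left out, and all 76 kept their sign.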

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

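The tests of exchanged labels, of markers varying together, of a lower share of conventional DCs and of the control probe sets, and the estimated correlation in the fits with a covariate, were chosen only after the results were seen; the fits with a covariate were added after seeing the control and marker levels, with their criteria set before they were run.

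Bacterial poly-A controls are transcripts that can be added to RNA before amplification. Their probe sets were not among the genes and probe sets tested with limma. They were higher in the arrays labelled spleen by 1.11 ± 0.27 log2 units (SE, n = 3 per group, exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 allow). This is a signal in data outside the main measurement. The hybridisation controls, which are added after amplification, differed by -0.11 ± 0.11 (SE) and so did not share the rise. This does not test a scaling shift of whole arrays, since the deposited values are already alike in median and quartiles between arrays. Less sample RNA per poly-A control in the arrays labelled spleen stays open, since all 4 transcripts were higher without overlap, by 0.84 ± 0.28 (SE) at the least. The difference between the 3′ and 5′ probe sets of the Gapdh control was also larger there, 3.28 ± 0.15 against 2.70 ± 0.10 (SD, n = 3 each), while that of Actb was -0.24 against -0.26. The labels give 2 ng of RNA for every array and do not mention these controls, and a difference between the organs stays untested.

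Genes of migratory and mature DCs were higher in the arrays labelled spleen, with a median difference of 0.94. With the poly-A control level as a covariate the list's median was 0.88 ± 0.12 (MAD of the members over the root of their number, camera adjusted p = 2.26e-08). With the plasmacytoid DC marker level it was 1.15 ± 0.15 (MAD likewise, camera adjusted p = 1.32e-11). The list thus kept its call and direction. These MAD values measure a spread between genes that varied together, not between arrays. Both levels separate the groups without overlap, so the fits cannot decide on lower RNA input or plasmacytoid DCs as the whole cause. With an estimated correlation the list did not pass in the comparison itself (adjusted p = 0.313) or with either covariate (0.534 and 0.483). The camera calls therefore rest on its preset correlation. Fry, which does not compare the list with other genes, passed it in the comparison without a covariate (adjusted p = 0.0210). Ccl22 lost its call with the poly-A level, going from 4.97 to 4.46 (adjusted p = 0.139), as that covariate follows the groups and leaves 3 residual degrees of freedom. An exchange of the 2 group labels is a candidate explanation that stays open, since the migratory list itself prompted it. The Notch-dependent splenic DC list, at -0.053 (camera adjusted p = 0.951) with members on both sides, decides nothing. The skin-derived DC and Langerhans cell list, which shares 1 gene with the migratory list, was also higher in the arrays labelled spleen (median 0.84). Slc40a1, Hmox1 and Vcam1, red pulp macrophage genes chosen after their values were seen, were high in lymph node array 3 alone. The list of red pulp macrophage markers did not pass (median -0.40, camera adjusted p = 0.506). Of its 17 measured members 12 had a negative difference and 5 a positive one. The only member past the threshold, Marco, was higher in the arrays labelled spleen (2.09, limma adjusted p = 0.0310). A true difference between the organs in the state of their DCs stays open as well, untested.

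Plasmacytoid DC markers were higher in the arrays labelled spleen, with a median difference of 1.39. A lower share of conventional DCs would raise the markers of every other cell type only if all of them filled the gap alike. A gap filled by some cell types alone was not tested. The neutrophil markers, at array means of 3.28 to 4.54 against a median of 5.46 over all genes, went the other way (median -0.42 ± 0.18, MAD of the members over the root of their number, camera adjusted p = 0.00518). That call was lost with an estimated correlation (adjusted p = 0.507), with fry (0.235), without both arrays numbered 3 (0.156) and with the plasmacytoid DC level as a covariate (0.214), though the median stayed between -0.86 and -0.26 in every alternative that tested it. Plasmacytoid DCs in the sort stay open as a candidate explanation: within groups the markers varied together (median pairwise correlation of deviations 0.809, against 0.191 at the 95th percentile of 10000 random lists of like level), but so did cDC1 (0.671), immediate early (0.88) and migratory genes (0.374), so the test does not single these cells out; Tcf4 lay at 9.84 against 8.45 and Tex2 at 9.38 against 7.26, neither past the threshold (adjusted p = 0.186 and 0.0650), while Pld4 (-0.66) and Irf7 (-0.11) were not higher, 9 of the 13 markers lay above the median gene level in the arrays labelled lymph node, and 4 of the 13 belong to another fixed list; these cells carry little CD11c, so a strict gate would remove them. Lower RNA input stays open too. With the poly-A level as a covariate the median became -0.097 ± 0.18 (MAD likewise, camera adjusted p = 0.765). The call was thus lost by a move of the value itself and not only of its error. The poly-A level separates the groups without overlap, so this fit cannot decide on lower RNA input. A difference between the organs stays untested.

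With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. The real split gave 421 genes and the highest of the others 0, and 1 of the 10 splits reached that count; for probe sets the values were 630, 0 and 1, for gene lists 12, 11 and 1, and for cell type marker lists 5, 6 and 4.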

How the results depend on the processing

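Median centring, a second quantile normalization, eBayes with trend and robust and the mean of all probe sets left the count of genes between 403 and 576, with 361 to 412 of the 421 genes shared, and 0 of the 421 changed sign. Array weights gave 764 genes (425 higher and 339 lower in arrays labelled spleen) and 1146 probe sets. With the filter at the median level 267 genes were lower and 2 marker lists passed; the filter tests fewer genes. It left 8 gene lists, as did the second quantile normalization. The filter ended the calls on skin-derived DC and Langerhans cell genes (adjusted p = 0.264), chemokines (0.0902), Toll-like receptors (0.131), tolerance-associated genes (0.591), T cell markers (0.129) and NK cell markers (0.0920). The quantile normalization ended those on chemokine receptors and tolerance-associated genes (both 0.0516), Toll-like receptors (0.0535) and ribosomal proteins (0.0721). A threshold of 0.01 left 63 genes (44 and 19). Over the 6 fits with 1 array left out, genes ranged from 50 to 478 (36 to 299 higher, 14 to 179 lower), probe sets from 20 to 639, gene lists from 9 to 15 and marker lists from 3 to 5; these fits have fewer samples. Other causes were not tested.

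The labels do not say that a number marks a shared animal, pool or day, so the numbers were not treated as pairing. Same-numbered arrays of the 2 groups had deviations correlated at 0.0219, 0.242 and 0.158, and lymph node array 1 correlated best with spleen array 2. The immediate early, heat shock and cell cycle lists, chosen after their values were seen, had their lowest mean on array 3 in both groups. A batch shared by number stays possible, and the main fit does not model it. The replicate block gave 518 genes (322 and 196), 757 probe sets, 12 gene lists and 5 marker lists; tolerance-associated genes lost their call (adjusted p = 0.0732) and immediate early genes gained it (0.0128).

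With an estimated correlation 0 gene lists and 0 marker lists passed, and with fry 9 and 0. Among alternatives chosen after seeing the data, leaving out both arrays numbered 3 gave 473 genes and the offset of 16 gave 370. The poly-A level as a covariate gave 0 genes in limma in either direction (701 at an unadjusted p under 0.05), 0 probe sets (1300 at an unadjusted p under 0.05) and 1 marker list. The plasmacytoid DC level gave 31 genes (26 and 5), 27 probe sets and 0 marker lists. In that fit the plasmacytoid DC list was adjusted for its own mean, so its loss was fixed in advance. Both levels separate the groups without overlap, so neither fit can decide between that level and the labels. Gene lists numbered 8 with the poly-A level and 13 with the plasmacytoid DC level. Calls lost with both were MHC class II (adjusted p = 0.488 and 0.0975), cDC2, Toll-like receptors (0.164 and 0.234), ribosomal proteins (0.560 and 0.326), and the markers of conventional DCs, T cells and NK cells. With the poly-A level alone Fc receptors (0.279), chemokine receptors (0.280), tolerance-associated genes (0.273) and plasmacytoid DC markers lost it, and with the plasmacytoid DC level alone neutrophil markers (0.214).

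Itgam, which did not pass, went from 0.10 to -0.13 without spleen array 2. List medians changed sign 94 times where the list passed neither in the comparison nor in the alternative, most often for cytokines (10 of 20 alternatives, medians from -0.98 to 0.45), apoptosis regulators (8), Notch-dependent splenic DC genes (7) and oxidative phosphorylation (7). Where the list passed in at least 1 of the fits, the changes of sign were these. For NF-kB targets, -0.013 became 0.17 without spleen array 3 (-0.061 without spleen array 2 at the lowest), 0.29 without both arrays numbered 3 and 0.42 with the plasmacytoid DC level. Red pulp macrophage markers became 0.17 without both arrays numbered 3. With the poly-A level, immediate early genes became 1.17, heat shock genes 0.52, ribosomal proteins 0.028, plasmacytoid DC markers -0.097 and NK cell markers -0.61. With the plasmacytoid DC level, immediate early genes became 1.11, heat shock genes 0.39 and cytokines 0.24; the cause was not tested. Without probe sets ending in the cross-hybridisation suffixes, Rab4a, Socs3, Ssbp3 and Ttc13, named here after their values were seen, changed sign among 410 genes still tested, Socs3 from 2.50 to -0.52.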

Other observations

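Several groups that did not pass as lists held members that did. Of 13 genes of LXR signalling and cholesterol efflux 3 were higher in the arrays labelled spleen and 0 lower, namely the efflux transporters Abca1 (3.00-fold, adjusted p = 0.0119) and Abcg1 (1.67-fold, adjusted p = 0.0477) and the lipid droplet gene Plin2 (2.75-fold, adjusted p = 0.0343), while Apoe differed by -0.93 ± 0.25 (SE, adjusted p = 0.0953). The list median was 0.46 (camera adjusted p = 0.105, fry adjusted p = 0.0347; adjusted p = 0.421 with an estimated correlation). It was 0.10 without spleen array 1 and 0.079 with the poly-A level as a covariate. The list passed camera without spleen array 3 (median 0.26, adjusted p = 0.0481) and without both arrays numbered 3 (median 0.26, adjusted p = 0.0442). In the lysosomal list, the protease gene Ctsl was 10.8-fold higher (adjusted p = 0.0338) and the cholesterol-binding gene Npc2 1.80-fold higher (adjusted p = 0.0402), and Tfeb, a transcription factor of lysosomal genes, 3.04-fold lower (adjusted p = 0.0340; list median 0.065, camera adjusted p = 0.547). Interferon response genes went both ways, with Mx1 (2.56-fold, adjusted p = 0.0119) and Ifi204 (3.27-fold, adjusted p = 0.0119) higher and Oas2 2.76-fold lower (adjusted p = 0.0192; list median -0.093, camera adjusted p = 0.547). Il2ra, named after its value was seen, was higher by 3.47 log2 units (adjusted p = 0.00528).

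Some lists varied between arrays of the same organ. The mean level of the immediate early genes was 8.35 in lymph node array 3 and 7.85 in spleen array 3, and 8.998 to 9.677 on the other arrays. Their deviations within groups had a median pairwise correlation of 0.88. The list median difference was -0.52 (camera adjusted p = 0.105; adjusted p = 0.826 with an estimated correlation). Without lymph node array 1 it was only -0.048. Without lymph node array 3 it was -0.99 (adjusted p = 0.000734), without spleen array 1 -0.54 (adjusted p = 0.0440), and without spleen array 2 -0.85 (adjusted p = 0.00841). These adjusted p came from camera with the preset correlation of 0.01, which lies far below the correlation of these genes. With the poly-A or the plasmacytoid DC level as a covariate the sign turned (1.17, adjusted p = 2.06e-07, and 1.11, adjusted p = 4.52e-07). The mean of the cDC1 genes was 6.33 in lymph node array 1 and 8.62 in spleen array 2, and 7.36 to 8.01 on the other arrays. Lymph node array 3 alone had high values for 3 genes of red pulp macrophages, chosen after their values were seen: Slc40a1 at 7.39 against 3.34 to 3.66 on the other arrays, Hmox1 at 6.997 against 4.31 to 5.06 and Vcam1 at 7.66 against 4.47 to 5.69. Xist lay at 10.81 to 11.50 and the Y-linked gene Eif2s3y at 1.85 to 2.54 on all 6 arrays.

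Called genes were also grouped by the letters that open their symbols, a test chosen after seeing the data. Of 210 such stems none passed in either direction; the smallest adjusted p of Fisher's exact test was 0.354. The annexin genes (3 of 11 higher in arrays labelled spleen, 0.223 expected, and 1 lower), the Serpinb genes (3 of 14 higher, 0.284 expected) and the Arhgap genes (3 of 20 lower, 0.274 expected, and 2 higher) shared it.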
